A study of Rattus norvegicus with 10 samples.

How the data were processed

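The data are poly(A)-selected RNA sequencing libraries from neonatal rat cardiomyocytes, 5 exposed to DMSO and 5 exposed to 1 µM palmitoylglycine, each for 24 h, per the labels. Per the labels' protocols, mRNA was captured on oligo(dT) beads and fragmented, and cDNA was primed with random hexamers. No strand-marking step is described, so reads from overlapping or antisense genes may not have been told apart. The authors deposited raw read counts per gene, one column for each library, per the file headers. The values are whole numbers that sum to a different total in each library. Per the submitters' processing notes, reads were trimmed with Trimmomatic and the genome build was mRatBN7.2. The aligner, the counting program, the annotation release, the strand setting and the rule that chose the genes listed are not given in the sources used here. Each count column was matched to a sample by the short name in that sample's description, and 0 columns were left unmatched.

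The table holds 15584 genes under Ensembl rat identifiers, of which 17 had a count of 0 in all libraries. The reference table used here gives no Ensembl identifiers, and 0 of the 15584 identifiers matched it. The 41 gene lists fixed before the data were examined (pathways, RNA quality and markers of other cell types) were therefore not evaluated, nor were GC content or gene length. Contributions from fibroblasts or other cells of the newborn heart were not assessed for the same reason. No coordinates are given.

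Library totals ranged from 56580073 to 78946785 counts. The labels' protocols describe PCR amplification and no molecular identifiers, so PCR duplicates may be among the counts. The libraries of a group were compared in pairs for identity. Over genes with a mean count of at least 10, the mean chi-square per gene ranged from 31.1 to 254 over the 20 pairs, where sampling noise alone gives about 1. No library was therefore a repeat of another, and all 10 were kept. The comparison cannot tell whether they came from separate cultures or animals.

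The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, glmQLFit and glmQLFTest, in R 4.3.3) with TMM factors, on the 15321 genes kept by filterByExpr (263 were removed), with the group as the only term and all 10 libraries. P-values are two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic, and intervals are unadjusted 95% intervals. Group means and SDs are of CPM scaled by the TMM factors. Single library measures and principal components (log2 CPM, prior count 2) were compared by exact permutation tests (scipy 1.17.1). The main design, the gene filter, the alternatives and the rule for the genes given were fixed before the data were examined, except where stated. Where fewer than 5 genes pass, that rule called for the 5 genes with a symbol that have the smallest p in each direction, besides Trpc5 and members of the gene lists. Without symbols it could not be applied as written. Only 2 identifiers in each direction are given, those with the smallest p among the 3321 genes with a mean of at least 1 CPM whose 5 palmitoylglycine libraries all lie on one side of the DMSO median. These last conditions were set in the rule for genes past the threshold, and were applied here after the data were seen.

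The groups share the numbers 1 to 5, and the labels do not say that a number marks a shared animal, culture or day. The deviations of same-numbered libraries from their group means correlated at 0.124, 0.125, 0.205, 0.362 and 0.30 for numbers 1 to 5. Every pair was above 0.1, so a pairing by number was considered, but the main test has no term for it. These correlations followed the subsets of libraries 1 to 3 and 4 to 5. The mean correlation was 0.223 for same-numbered libraries, 0.24 for other libraries of the same subset across groups and −0.252 between subsets. With deviations taken from the means of each group within a subset, the correlations of same-numbered libraries were all below 0, at −0.0526, −0.0161, −0.0675, −0.0566 and −0.0566 for numbers 1 to 5, so no pairing by number was seen beyond the subsets. The values of numbers 4 and 5 are equal by construction, since 2 libraries deviate from their mean by opposite amounts. Only 2 of the 10 libraries correlated best with their own number. Fits with the replicate number as a block, and fits with a term for the subsets (chosen after seeing the data), are given beside the main result.

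The alternatives were median-of-ratios size factors, total counts alone, DESeq2 (1.42.0) with its default filtering (345 of its adjusted p-values were NA and were left so), limma-voom (limma 3.58.1) with quality weights, no filter, a minimum mean of 5 CPM, a minimum fold of 1.2, the replicate block, and leaving out each library. Added after seeing the data were the subset term in edgeR, DESeq2 and limma-voom, each subset alone, DESeq2 with the replicate block, robust estimation, and prior counts of 0.5 and 5 for the principal components. The scripts were tested on simulated data, drawn for the 15321 genes from the means of each subset, the real library sizes and the fitted dispersions, with 200 genes above 1 CPM changed by known folds, 50 for each fold. Of 15121 unchanged genes, edgeR called 2 without further terms, 9 with the subset term and 13 with the replicate block, and DESeq2 called 18. At an unadjusted p under 0.05 were 356 of them in edgeR without further terms, 746 with the subset term and 713 with the replicate block, and 383 in DESeq2. Of genes changed by 1.5-fold and 2-fold, edgeR recovered 30% and 70% without further terms. It recovered 48% and 88% with the subset term and 44% and 84% with the replicate block. DESeq2 recovered 50% and 88%. The same simulated data also held 4-fold and 8-fold changes.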

Results

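Messenger RNA was sequenced from neonatal rat cardiomyocytes, primary heart muscle cells taken from newborn rats. The cells had been exposed for 24 h either to 1 µM N-palmitoylglycine, an amide of palmitic acid and the amino acid glycine, or to the solvent DMSO. The series title ties this lipid to TRPC5, a calcium-permeable cation channel, and to Brugada syndrome, an inherited arrhythmia disorder. The comparison addressed which transcripts differed in abundance after exposure to the lipid. There were 5 libraries per group, numbered 1 to 5 in each. The labels do not say whether the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Total counts per library ranged from 56580073 to 78946785. They averaged 64937112 ± 7656431 (SD, n = 5) with palmitoylglycine and 67895881 ± 6662665 (SD, n = 5) with DMSO, a difference within the spread between replicates (two-sided exact permutation test, p = 0.54, adjusted p over 8 library measures and components 0.898). The most abundant gene took 3.17% ± 0.678 (SD, n = 5) of the counts with palmitoylglycine and 3.19% ± 0.339 (SD, n = 5) with DMSO (two-sided exact permutation test, p = 0.944, adjusted p 0.944). The deposited table names its genes by Ensembl rat identifiers and does not pair them with symbols, so symbols were not used here. Trpc5 and the 41 gene lists fixed for this comparison were therefore not analysed here.

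Across all 10 libraries, edgeR's quasi-likelihood test called no gene between palmitoylglycine and DMSO at an adjusted p under 0.05, whereas DESeq2 called 134 genes. The spread between libraries in the edgeR test included a difference between subsets of the libraries, described below. In edgeR, 0 of 15321 genes passed this threshold and the smallest Benjamini-Hochberg adjusted p was 0.372. At an unadjusted p under 0.05 there were 1584 genes, 10.3% of those tested, of which 813 had the higher mean with palmitoylglycine and 771 the lower. In the simulated counts, 356 of 15121 unchanged genes were under 0.05 in this test, so 10.3% is not to be read against 5%. Of 100 splits of the libraries, the real one included, 8 gave at least 1584 genes. The fold changes were small. Their centre at 0 follows from the scaling of the libraries, so a shift shared by all transcripts would not appear. The 5th percentile of the log2 fold changes was −0.43 and the 95th 0.42, and 78.7% of genes had an estimate within 1.2-fold of DMSO. An estimate above 2-fold higher was found for 84 genes and above 2-fold lower for 112 genes. These 196 genes were mostly of low abundance, with a median of 0.703 CPM (counts scaled to a common library total) against 19.4 CPM over all genes tested.

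The unadjusted 95% intervals describe the size of the difference for each gene taken singly, so some will miss the true value. They do not tell what would pass the adjusted threshold. The median half-width of a gene's unadjusted 95% interval was 0.30 on the log2 scale, a factor of 1.23. The whole interval lay within 2-fold of no change, in either direction, for 12844 genes, 83.8% of those tested. It lay within 1.5-fold for 9945 genes, 64.9%. Among the 1511 genes under 1 CPM the median half-width was 1.01, among the 3959 genes from 1 to 10 CPM it was 0.45, and among the 1898 genes over 100 CPM it was 0.20. Counts were simulated for these 15321 genes and this 5 against 5 comparison, with changes given to genes above 1 CPM. The same test recovered 30% of genes changed by 1.5-fold, 70% of those changed by 2-fold and 96% of those changed by 4-fold. These rates hold for 50 genes at each fold, up to 8-fold, in the same data, with genes drawn independently. A response made only of small changes was not simulated, and its recovery could be lower.

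The count of genes past the threshold differed between tools. DESeq2 called 134 of 15584 genes at an adjusted p under 0.05, whereas limma-voom with quality weights called 0, with 3144 genes at an unadjusted p under 0.05. Of the DESeq2 calls, 76 were higher with palmitoylglycine, with a median log2 fold change of 0.57, and 58 were lower, with a median of −0.61. In the simulated counts, DESeq2 called 18 of 15121 unchanged genes and edgeR without further terms 2. With the replicate number as a block, edgeR still called 0 genes, with 2389 at an unadjusted p under 0.05, and DESeq2 called 454 genes. The DESeq2 count fell to 38 without DMSO library 1, 33 without DMSO library 2, and 30, 59 and 39 without palmitoylglycine libraries 1, 2 and 3, and was 452 and 433 without palmitoylglycine libraries 4 and 5.

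The genes with the smallest p in edgeR, 2 in each direction among genes of at least 1 CPM whose palmitoylglycine libraries all lay on one side of the DMSO median, are given by identifier. ENSRNOG00000059827 averaged 29.4 CPM ± 2.50 (SD, n = 5) with palmitoylglycine and 20.3 CPM ± 2.09 (SD, n = 5) with DMSO. Its log2 fold change was 0.53 with a standard error of 0.09. ENSRNOG00000033173 averaged 4.20 CPM ± 0.586 (SD, n = 5) with palmitoylglycine and 2.38 CPM ± 0.340 (SD, n = 5) with DMSO, a log2 fold change of 0.82 with a standard error of 0.15. On the lower side, ENSRNOG00000006526 averaged 162.2 CPM ± 5.73 (SD, n = 5) against 219.3 CPM ± 18.8 (SD, n = 5) with DMSO. Its log2 fold change was −0.43 with a standard error of 0.07. ENSRNOG00000033299 averaged 329.4 CPM ± 27.2 (SD, n = 5) against 438.0 CPM ± 13.6 (SD, n = 5) with DMSO, a log2 fold change of −0.41 with a standard error of 0.07. All 5 palmitoylglycine libraries lay outside the range of the DMSO libraries in each of these genes, which were chosen for their small p. Their edgeR adjusted p was 0.372 each. In limma-voom with quality weights it was 0.0648 each, closer to the threshold but not past it, and 0.0712 each with the subset term. In DESeq2 the adjusted p was 5.6e-04 for ENSRNOG00000059827, 0.0011 for ENSRNOG00000033173, and 5.2e-05 for both genes on the lower side.

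**Figure D1:**
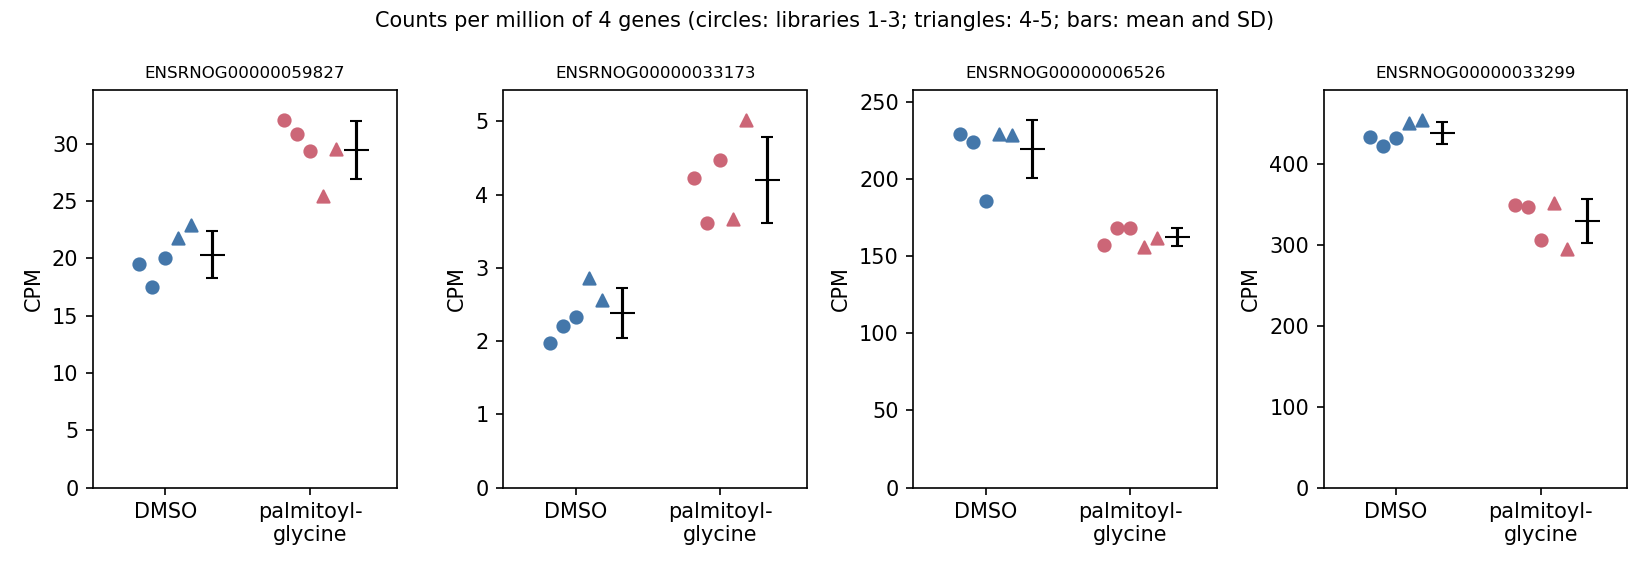
CPM (vertical axes, starting at 0) in each library of the 2 groups for 4 genes, with circles for libraries 1 to 3, triangles for libraries 4 and 5, and a bar for the mean and SD of 5 libraries. In ENSRNOG00000059827 the palmitoylglycine libraries lay between 25.4 and 32.1 CPM and the DMSO libraries between 17.5 and 22.9 CPM.

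The libraries fell into 2 subsets that crossed the treatment. The first principal component, with 32.4% of the variance, placed libraries 1 to 3 of both groups between −34.0 and −14.8 and libraries 4 and 5 of both groups between 32.8 and 43.4. The second component, with 15.9% of the variance, separated the treatment groups without overlap, with means of −17.9 ± 12.6 (SD, n = 5) for palmitoylglycine and 17.9 ± 18.9 (SD, n = 5) for DMSO. Its two-sided exact permutation p was 0.00794, the smallest that 5 against 5 libraries allow, and 0.0635 after adjustment over the 8 library measures and components tested. That adjusted value could not have gone under 0.05 without small p-values among the others. The absence of overlap depended on the prior count added to the counts. With 5 in place of 2 the groups were also apart, the highest palmitoylglycine library at −3.46 and the lowest DMSO library at 0.65 (exact permutation p = 0.00794), whereas with 0.5 these lay at 0.05 and −0.18 (exact permutation p = 0.0159). On this component, palmitoylglycine libraries 1 to 3 lay between −36.5 and −18.8 and DMSO libraries 1 to 3 between 10.8 and 39.0. The corresponding values were much closer in libraries 4 and 5, at −12.0 and −2.13 with palmitoylglycine and 0.46 and 2.10 with DMSO.

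**Figure D2:**
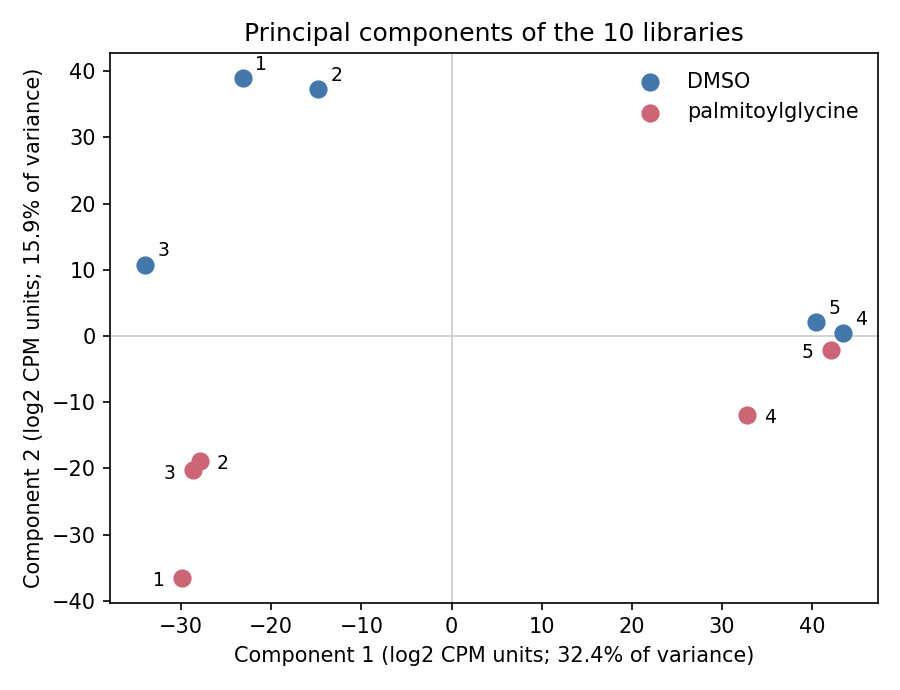
First and second principal components (log2 CPM units) of the 10 libraries, coloured by treatment and numbered by replicate. Libraries 1 to 3 and libraries 4 and 5 lie on opposite sides of the first component in both groups, and the groups are separated on the second, with a prior count of 2.

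The comparison was repeated within the subsets and with a term for them, after the subsets had been seen. In libraries 1 to 3 alone, edgeR's quasi-likelihood test called 697 genes at an adjusted p under 0.05, 412 higher and 285 lower with palmitoylglycine. In libraries 4 and 5 alone it called 5 genes, 3 higher and 2 lower, and no gene was called in both subsets. With the subset as a term over all 10 libraries, edgeR called 0 genes, with a smallest adjusted p of 0.109 and 2925 genes (19.1%) at an unadjusted p under 0.05. Without palmitoylglycine library 4 this fit called 69 genes, and without any other single library 0 or 1. The share of genes at an unadjusted p under 0.05 in this fit was 7.81% under 1 CPM, 16.5% from 1 to 10 CPM, 20.4% from 10 to 100 CPM and 28.1% over 100 CPM. DESeq2 with the subset term called 907 genes, 475 higher and 432 lower. The difference between the subsets in the response itself was tested as an interaction, and 9 of 15321 genes passed an adjusted p of 0.05 in edgeR. Across 15232 genes, which are not independent replicates, the fold changes in the 2 subsets correlated with Pearson's r = 0.106 and Spearman's rho = 0.176.

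**Figure D3:**
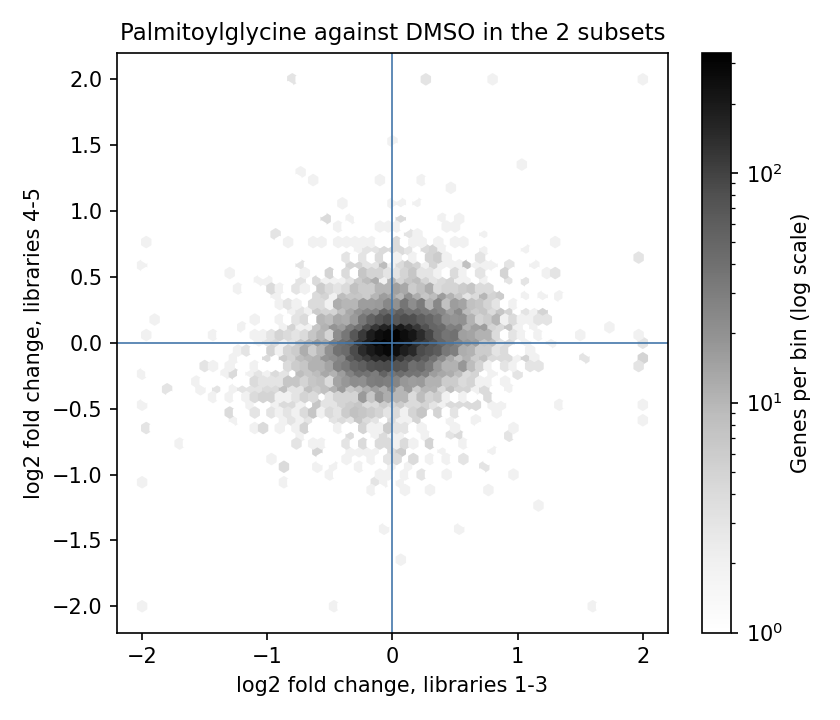
Log2 fold change of palmitoylglycine against DMSO in libraries 1 to 3 (horizontal axis) and in libraries 4 and 5 (vertical axis) for 15232 genes, binned, with the number of genes per bin in grey on a log scale and values beyond the axes drawn at their ends. Most genes lie near 0 on both axes, and the fold changes of the 2 subsets are weakly correlated, with Pearson's r = 0.106.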

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

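In the DMSO group, library 3 stood apart from the others for ENSRNOG00000006526, at 185.8 CPM against 224.0 to 229.1 CPM in the other DMSO libraries. The gap was large for 5 values. Of 24 sets of 5 values examined in this way (library measures, components and the 4 genes given), 1 stood out, and chance gives about 1 in 20. The log2 fold change of ENSRNOG00000006526 was −0.43 with all libraries and −0.49 without DMSO library 3, with an edgeR adjusted p of 0.0768. Over all alternatives its adjusted p ranged from 5.3e-06 in DESeq2 with the subset term to 1 in edgeR against a minimum fold of 1.2.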

How the results depend on the processing

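The count of 0 genes past an adjusted p of 0.05, in both directions, was also found with median-of-ratios size factors, total counts alone, limma-voom with quality weights, no filter, a minimum of 5 CPM, a minimum fold of 1.2, the replicate block and, added after seeing the data, robust estimation, the subset term and limma-voom with the subset term. Leaving out each library in turn gave 0 to 1 genes (higher: 0 to 1), with 1 called without DMSO library 2 and 1 without palmitoylglycine library 1. The exceptions were DESeq2 (134 genes, 76 higher and 58 lower), DESeq2 with the replicate block (454, 200 and 254), DESeq2 with the subset term (907, 475 and 432), libraries 1 to 3 alone (697, 412 and 285) and libraries 4 and 5 alone (5, 3 and 2), of which all but the first were added after seeing the data. The cause of the difference between edgeR and DESeq2 was not tested. At an unadjusted p under 0.05, edgeR's 1584 genes became 407 against a minimum fold of 1.2, 2389 with the replicate block, 2925 with the subset term, 3814 in libraries 1 to 3 alone, 478 in libraries 4 and 5 alone, and 1055 to 2167 when leaving out each library, the lowest without DMSO library 1. It was 1797 in DESeq2 (2469 with the block, 3109 with the subset term) and 3144 in limma-voom (3408 with the subset term). The 4 genes given kept their direction in all 99 alternative values and passed an adjusted p of 0.05 in 15 of them. They were chosen from these same libraries for a small p and a shared direction, so the unchanged direction was likely beforehand. The fixed gene lists were not run, since the identifiers were not paired with symbols, nor were other pseudocounts for normalized values, which the table does not hold. The second component's difference of −35.9 was −39.7 and −33.1 with prior counts of 0.5 and 5, added after seeing the data, with overlap between the groups at 0.5 and none at 5. The median half-width of a gene's 95% interval was 1.01 (log2) under 1 CPM and 0.20 over 100 CPM, so low counts limit the rarer genes.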

Other observations

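The tests here that use the subsets of libraries 1 to 3 and 4 to 5, or DESeq2 with a block, and the split count of the genes at an adjusted p, were chosen after the result they examine had been seen. The subsets differed in far more genes than the treatment groups. With the treatment as the other term, edgeR's quasi-likelihood test called 4500 of 15321 genes (29.4%) between them, 2287 higher and 2213 lower in libraries 4 and 5, of which 592 differed by more than 2-fold. The biological coefficient of variation was 26.3% with the group alone and 19.9% with the subset as a further term. Pairs of libraries from different treatments in the same subset correlated at a mean r of 0.972, and pairs from the same treatment in different subsets at 0.961. Which genes these are was not analysed by name.

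The labels give no batch that follows these subsets, and no biological explanation was tested. Depth as the whole cause is argued against, since 97.1% of the 4500 genes were still called after every library was thinned to the same total. A few abundant genes are argued against as well, since 97.8% of the other genes were still called without the 100 most abundant. Of the 10 ways to part the 5 replicate numbers into 3 and 2, only 1, the observed one, gave as many genes (4500, the highest other 1), but 10 ways are too few for a share under 0.05. Separate cultures, days or sequencing runs may underlie the subsets, and remain open.

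The treatment was compared with other splits of the same libraries. Of the splits into 5 and 5, 100 were drawn at random with the real one included. At an unadjusted p under 0.05 in edgeR, 8 of the 100 gave at least the real 1584 genes, the highest other 4527. Chance was therefore not excluded for that count over unrestricted splits. Apart from the real one, each of the 8 was unbalanced for libraries 1 to 3, so it held part of the difference between the subsets. Among the 50 drawn splits with 3 of these libraries in each group, the real one included, the median was 215 genes and the highest other 1347. At an adjusted p under 0.05 the real count is 0, which all 100 reach by construction (highest other 1328), so that count tests nothing. The 5 splits that put 5 of the 6 libraries numbered 1 to 3 in the same group called 10 to 1328 genes, which points to the subsets as a structure of the samples. The splits that keep 3 and 2 libraries of each subset per group number 60. Only the real one gave as many as its 2925 genes with the subset term at an unadjusted p, the highest other 2702. Chance is argued against but not excluded, since the subset term was chosen after seeing the data and the split counts were not adjusted for their number. Leaving out single libraries in this fit gave 2045 to 3472 genes, a wider range than the gap to 2702. The count of 2925 rests mainly on libraries 1 to 3, whose own 10 splits are too few for a share under 0.05. The 5 other splits that keep the treatment grouping of libraries 1 to 3, either way round against libraries 4 and 5, gave 1614 to 2702 genes. The 54 that do not gave 250 to 1319. Of these 54, the 18 that keep the grouping of libraries 4 and 5 also gave 250 to 1319.

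In DESeq2, 1 of these 60 splits, the real one, gave as many genes as the real 134 at an adjusted p under 0.05 (highest other 49), and with the subset term likewise 1 of 60 gave as many as 907 (highest other 677). These shares are under 0.05 among those splits only, since splits that are unbalanced for the subsets were not run in DESeq2. They were not adjusted for the number of split counts made. The splits that part all 5 same-numbered pairs number 16, too few for a share under 0.05, with 2389 genes at an unadjusted p in edgeR (highest other 2241) and 454 in DESeq2 (highest other 342), each reached by 1 split, the real one. The 10 splits of libraries 1 to 3 alone are also too few, with 697 genes in the real split and 5 in the highest other, and 1 reaching the real count. A response to palmitoylglycine too small for edgeR's adjusted threshold over 10 libraries is one hypothesis that these counts leave open.

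Libraries 1 to 3 gave 697 calls and libraries 4 and 5 gave 5. Fewer libraries may account for part of this. The 9 draws of 2 against 2 libraries from numbers 1 to 3 gave a median of 13 calls. They gave 0, 6, 8, 8, 13, 28, 64, 214 and 604, all but the lowest above the 5 of libraries 4 and 5. A different response in libraries 4 and 5 stays open. Of 695 genes called in libraries 1 to 3, 65.8% had the same direction in libraries 4 and 5 by differences of mean log2 CPM. That share was above the 57.1% of the highest other labelling of those 4 libraries. It was below the share set in advance as arguing against a different response. With only 6 labellings, chance could not be excluded. By edgeR's estimates the share was 66.9%, against 56.6% among all genes, and of the 695 genes 31 had the same direction and 3 the opposite at an unadjusted p under 0.05 in libraries 4 and 5. The test of the difference itself called 9 genes in edgeR, with 1636 at an unadjusted p under 0.05.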
